A study of Raphidocelis subcapitata with 45 samples.

How the data were processed

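Transcript levels were measured in Raphidocelis subcapitata, a unicellular freshwater green alga widely used in toxicity testing, after 24 h of exposure to sertraline hydrochloride, a selective serotonin reuptake inhibitor used as an antidepressant. Per the labels' protocols, a culture in exponential growth was exposed in sealed deep-well plates, with 5 wells per concentration on a plate, and RNA was extracted from homogenates pooled over 3 plates. Libraries were made with a 3′ mRNA kit (QuantSeq) that primes on poly(A) tails and carries molecular identifiers. Groups were taken from the concentration in each sample title, which gives a solvent control and 8 nominal sertraline concentrations (50, 125, 314, 784, 1960, 4900, 12249 and 30623 µg/L), each with replicates lettered A to E. The series' design text rounds the highest concentrations differently and gives another solvent content than the treatment protocol, so the concentrations in the sample labels were used and no solvent content is given. Wells with copper sulfate or atrazine were not analysed here. The labels do not say which wells a letter stands for and name no separate cultures, so the p-values measure the spread between these libraries, which may be technical, and not the spread between cultures.

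The authors deposited 1 table of normalized values on a log scale, read here as log2, for 7291 genes and 41 libraries. Per the submitters' processing notes, the tools used were bcl2fastq 2.20.0, fastp 0.23.2, STAR 2.7.10a, SAMtools 1.15.1, featureCounts 2.0.6 and DESeq2; their order, settings and any removal of duplicate molecules are not given in the sources used here, nor are the genome build and the transform. The values ran from 1.19 to 12.6, the library medians from 4.55 to 4.73, and no gene had 2 equal values, as a regularized log would give, but this does not settle the transform, since whether the genes kept include counts of 0 is unknown. If it was a regularized log, which pulls weakly measured genes towards their mean, changes of low genes would be understated. If the log base is not 2, every fold given here changes with it. The table holds no read counts, so the depth of each library is unknown, and neither intervals from counts nor count models could be used. The identifiers reach number 13433, so the 7291 genes are part of the numbered set, and the filter that chose them is not given in the sources used here. Of the 45 labelled libraries, 4 were not analysed here, since the table used here has no values for them: replicates D and E at 12249 µg/L and B and E at 30623 µg/L. These groups therefore had 3 libraries and the others 5. No 2 libraries were copies of each other (highest correlation 0.975).

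The table gives genes by identifier only, without product names, and no annotation was used here. The 37 gene lists fixed from product-name patterns before the data were examined, which included antioxidant enzymes, heat shock proteins, photosynthesis and ribosomes, were therefore not tested, and the genes named are limited to 2 that rose and 2 that fell. They are the genes with the highest and lowest log2 changes at the concentration with most genes past the threshold, among genes past it whose treated libraries all lay on one side of all control libraries.

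The tests were chosen to fit log values. All 41 libraries entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes with an intensity trend, 32 residual and 24.4 prior degrees of freedom), without a filter or a pseudocount. Each concentration was compared with the control, 12249 with 4900 and 30623 with 12249 µg/L, and a moderated F test asked whether a gene differed in any group. A separate limma fit tested a slope over the concentration rank. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 7291 genes of each comparison, and the threshold was an adjusted p of 0.05. A contrast of 1960 with 784 µg/L, the scaling by quantiles, the breakdown by expression tercile, the fit without the groups from 1960 µg/L up and the sets of genes followed across concentrations were chosen after the data had been seen. Benchmark concentrations were computed for genes past the F test with a log2 change of at least 1 at some concentration. Group means were made monotone by isotonic regression, and the concentration at which the curve departed from its control value by 1 residual SD was interpolated on a log10 scale, with crossings below the lowest concentration set to 50 µg/L. Their error came from 100 bootstrap draws of libraries within groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

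The tests were checked on simulated data built from each gene's mean and residual SD, scaled by each group's spread. For 784 µg/L, with 200 of 7291 genes changed, the fit recovered 32% of the genes with a log2 change of 0.5, 96% of those with 1 and 100% of those with 2. For 30623 µg/L it recovered 28%, 88% and 100%, but 30.7% of its calls were unchanged genes. The model shares 1 spread over groups that differ in spread. With no change simulated, it called 14 genes at 30623 µg/L and at most 1 at each other concentration. The group spread was a median SD over genes, which runs low in small groups, most with 3 libraries. The simulated noise was therefore somewhat too small, and false calls may be more numerous than given. Simulations of unchanged groups for neighbouring concentrations used the same scaling. A fit on the 2 groups alone, which shares no spread with the other groups, was among the alternatives. A slope of 0.25 per concentration rank was recovered for 100% of 200 genes, and 87.5% of 200 genes raised by 3 from 4900 µg/L up were given a benchmark concentration between 1960 and 4900 µg/L. Another alternative kept only genes with a mean log2 value of at least 5.64, the log2 of 50, called a mean of at least 50 below. The others were centring of libraries on the median log2 ratio, quantile scaling and the replicate letter as a block. Library weights and a minimum log2 change of 1 were also used. Each library was left out in turn, and benchmark concentrations were repeated with other departures, thresholds, curves and groups.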

Results

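Transcripts of R. subcapitata were profiled in 41 libraries after 24 h without sertraline or at 1 of 8 nominal concentrations between 50 and 30623 µg/L. The solvent control and the groups from 50 to 4900 µg/L had 5 libraries each, and the 12249 and 30623 µg/L groups had 3 each. The deposited table gave 7291 genes as log2 normalised expression, with library medians between 4.55 and 4.73. Read depth per library is unknown. The design asks at which concentrations, and how far, transcript levels departed from the solvent control. By its title the study was concerned with reactive oxygen species, but antioxidant genes were not analysed here because the genes carry identifiers without names.

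The libraries from 1960 µg/L up lay apart from those of the lower concentrations, and those at 12249 and 30623 µg/L overlapped on the first principal component. This component held 42.2% of the variance. Its score was -20.1 ± 1.63 (SD, n = 5) in the control and -20.3 ± 1.67 (SD, n = 5) at 784 µg/L, and it then took the values 6.69 ± 5.44 (SD, n = 5) at 1960, 27.6 ± 11.3 (SD, n = 5) at 4900, 53.7 ± 7.75 (SD, n = 3) at 12249 and 52.3 ± 5.85 (SD, n = 3) at 30623 µg/L. The third component, with 9.10% of the variance, set the 1960 µg/L libraries (-25.4 ± 1.69, SD, n = 5) apart from both the control (2.28 ± 1.70, SD, n = 5) and the 12249 µg/L libraries (21.0 ± 3.43, SD, n = 3). Libraries of one group also differed more from each other at high concentrations. The median SD of a gene was 0.24 in the control, 0.25 at 784, 0.32 at 1960, 0.36 at 4900, 0.34 at 12249 and 0.42 at 30623 µg/L, all on the log2 scale. These SDs came from 5 libraries per group, but from 3 at 12249 and 30623 µg/L. A median SD runs low with fewer libraries, so the values of these groups are not directly comparable with the others.

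**Figure D1:**
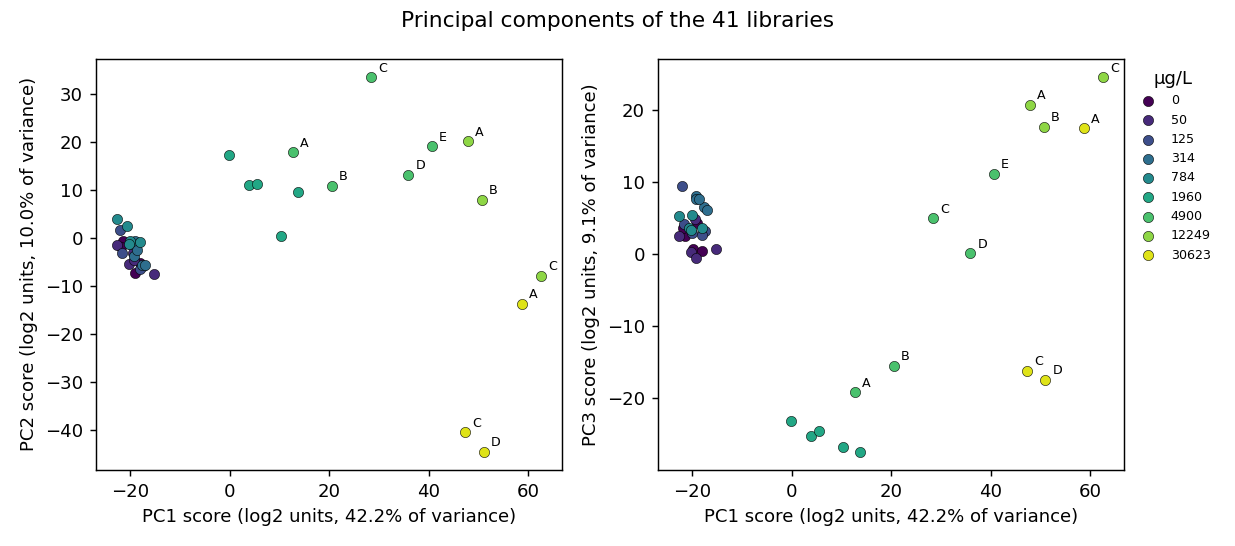
Scores of the 41 libraries on the first principal component (x axis) against the second and the third (y axes), in log2 units; each point is 1 library, coloured by nominal sertraline concentration in µg/L, and letters mark replicates from 4900 µg/L up. The libraries from 0 to 784 µg/L lie together, the 4900 µg/L libraries spread between the 1960 and 12249 µg/L groups, and C and D of 30623 µg/L lie apart from A.

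No gene passed the threshold at 50 or 125 µg/L in limma's moderated test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 91 genes at 50 and 241 at 125 µg/L, against the 365 that chance would give. Without the groups from 1960 µg/L up, the median residual SD of a gene was 0.26 in place of 0.33 on the log2 scale. That fit had 322 genes at 50 and 626 at 125 µg/L at an unadjusted p under 0.05, and called 0 and 1 after adjustment.

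At 314 µg/L, 53 genes differed from the control, and 51 of them were lower. At 784 µg/L, 213 genes differed, of which 159 were lower and 54 higher. The number higher was 30 without replicate E of 784 µg/L, and 35, 31 and 34 without control replicate A, B or D. Of the larger changes most were falls: 83 of the 91 genes that passed the threshold with a log2 change of at least 1 at 784 µg/L were lower, and the strongest fall was -3.08 against a strongest rise of 1.87. More rises were called in fits that do not share the spread of the high groups. With the 2 groups compared alone there were 40 genes higher and 126 lower at 314 µg/L and 157 and 277 at 784 µg/L, and with the groups from 1960 µg/L up left out of the fit 43 and 119 at 314 and 227 and 345 at 784 µg/L.

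The response widened at 1960 µg/L, where 1613 genes (22.1%) differed from the control, 716 higher and 897 lower. The strongest rise was 4.19 and the strongest fall -2.75 on the log2 scale, with a median standard error of 0.21. A direct contrast with 784 µg/L found 762 genes higher and 861 lower at 1960 µg/L, and 805 and 815 when libraries were centred. At 4900 µg/L, 2452 genes (33.6%) differed from the control, 1084 higher and 1368 lower. Among the genes with a mean of at least 50, falls outnumbered rises more clearly, with 180 higher and 476 lower at 1960 and 301 and 573 at 4900 µg/L. Among changes of at least 1 on the log2 scale at 1960 µg/L, 189 were higher and 182 lower.

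At the highest concentrations about as many genes differed from the control as did not. There were 3623 (49.7%) at 12249 µg/L, 1719 higher and 1904 lower, and 3927 (53.9%) at 30623 µg/L, 1879 higher and 2048 lower. A log2 change of at least 1 was reached by 1639 of these genes at 12249 µg/L, 835 higher and 804 lower, and by 1949 at 30623 µg/L, 1013 higher and 936 lower. Among the genes with a mean of at least 50, 513 were higher and 727 lower at 12249 µg/L and 286 and 990 at 30623 µg/L. The majority of all called genes turned when libraries were centred on their median log2 ratio, with 1869 higher and 1749 lower at 12249 µg/L and 1970 higher and 1939 lower at 30623 µg/L. Direction went with expression level at 30623 µg/L: in the lowest expression tercile 853 genes were higher and 158 lower, with a median log2 change of 0.33, and in the highest tercile 409 were higher and 1303 lower, with a median of -0.52. Under quantile scaling the lowest tercile had 718 higher and 278 lower, with a median of 0.18, and the highest 554 higher and 1220 lower, with a median of -0.42. Scaling to equal ranges itself tends to raise low genes and lower high ones where changes are large, so it does not test this link. At 12249 µg/L the medians as deposited were 0.03 and -0.18.

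**Figure D2:**
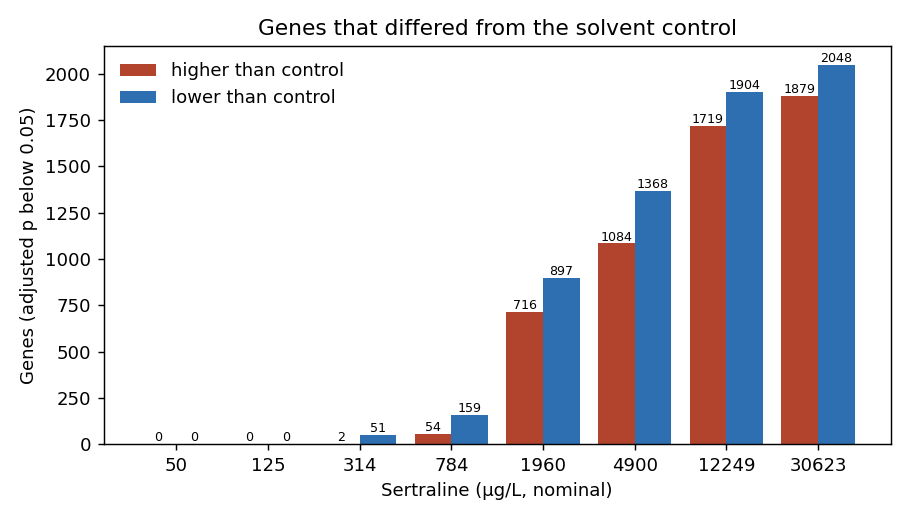
Number of genes (y axis) with an adjusted p under 0.05 against the solvent control at each nominal sertraline concentration (x axis, µg/L), split into genes higher (red) and lower (blue) than the control. No gene passes at 50 or 125 µg/L, lower genes outnumber higher ones at 314 and 784 µg/L, and the 2 directions are close in number from 1960 µg/L up.

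Neighbouring high concentrations differed from each other. Between 12249 and 4900 µg/L, 1557 genes differed, 852 higher and 705 lower at 12249 µg/L, a majority that turned under quantile scaling (655 higher and 743 lower) and among genes with a mean of at least 50 (388 and 392). Between 30623 and 12249 µg/L, 2089 genes differed, 942 higher and 1147 lower at 30623 µg/L. Among the genes with a mean of at least 50 these were 88 and 762, and among changes of at least 1 on the log2 scale the majority turned, with 402 higher and 297 lower. With the 2 groups alone, which changes both the spread and the residual degrees of freedom, the counts were 417 and 211. Without replicate C of 12249 µg/L the first was 792, and the second was 1277 without replicate A of 12249, 1247 without C of 30623 and 1153 without D of 30623 µg/L.

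The 2 genes that rose most at 30623 µg/L were near their control level up to 784 µg/L. Rsub_11992 was at 4.40 ± 0.26 (SD, n = 5) in the control and 4.26 ± 0.11 (SD, n = 5) at 784 µg/L, and rose 16.3-fold at 1960 µg/L, to 8.42 ± 0.45 (SD, n = 5). At 30623 µg/L it was 63.1-fold above the control, a log2 change of 5.98 ± 0.24 (SE) with an adjusted p of 6.38e-28 in limma's test. Rsub_09789 rose by 2.14 ± 0.26 (SE) at 1960 and by 4.82 ± 0.30 (SE) at 30623 µg/L, with an adjusted p of 5.53e-20 at 30623 µg/L in limma's test. It was a low gene in the control, at 2.71 ± 0.26 (SD, n = 5).

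The 2 genes that fell most at 30623 µg/L had already fallen at 314 µg/L, and both stood nearer to the control at 1960 µg/L than at 784. Rsub_00393 fell by 1.80 ± 0.28 (SE) at 314 and fell by 1.99 ± 0.28 (SE) at 784 µg/L (limma adjusted p = 4.92e-05 and 1.23e-06). At 1960 µg/L it was 0.61 ± 0.28 (SE) above the control, which did not pass the threshold (limma adjusted p = 0.116). It fell by 2.99 ± 0.33 (SE) at 12249 and fell by 2.86 ± 0.33 (SE) at 30623 µg/L, with an adjusted p of 8.26e-11 in limma's test at 30623 µg/L. At 4900 µg/L its libraries spread widely, at 8.56 ± 1.28 (SD, n = 5). Rsub_00682 fell by 1.05 ± 0.19 (SE) at 784, fell by 0.60 ± 0.19 (SE) at 1960 and fell by 2.80 ± 0.22 (SE) at 30623 µg/L, the last with an adjusted p of 1.28e-16 in limma's test. Of the 3927 genes called at 30623 µg/L, 2966 had all 3 treated libraries on one side of all 5 control libraries. Among all 7291 genes 3086 did, where chance would give 3.57% of genes.

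**Figure D3:**
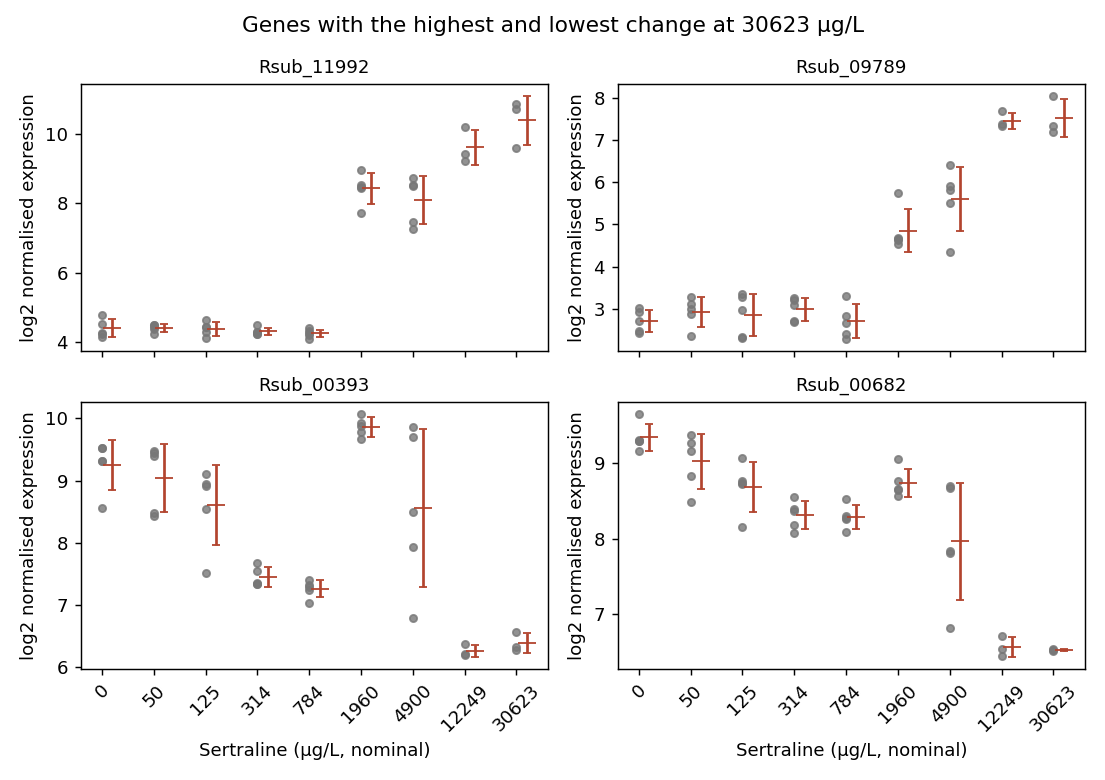
Log2 normalised expression (y axis) of the 2 genes with the highest and the 2 with the lowest change at 30623 µg/L, against nominal sertraline concentration (x axis, µg/L); grey points are libraries and red marks the group mean with its SD (n = 5, or 3 at 12249 and 30623 µg/L). Rsub_11992 and Rsub_09789 rise from 1960 µg/L up, while Rsub_00393 is low at 314 and 784 µg/L, at 9.86 at 1960 µg/L and low again at 12249 µg/L.

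Part of the genes that were lower at 314 µg/L did not follow a monotone course. All 51 were also lower at 784 µg/L, where their median log2 change was -1.57 (quartiles -1.98 and -1.08). At 1960 µg/L the set was split: the median change was 0.07 with quartiles -1.29 and 0.50, and 22 were lower than the control, 9 higher and 20 not called. At 12249 µg/L 46 of the 51 were lower than the control, some of them without having left that call at 1960 µg/L, and the set's median was -2.12. The differences between concentrations were tested directly in the same limma fit: 37 of the 51 were higher at 1960 than at 784 µg/L, 30 were lower at 12249 than at 1960 µg/L, and 29 did both. The 314 µg/L and control libraries, on which these genes were chosen, do not enter these differences. Against the 125 µg/L libraries in place of the control, the set's median was -1.07 at 784, 0.46 at 1960 and -1.45 at 12249 µg/L. In single libraries the set's median against the control mean lay between -0.07 and 0.17 at 1960 µg/L and between -1.67 and -1.41 at 784 µg/L. At 125 µg/L replicate B stood at -1.46, and the other 4 libraries lay between -0.37 and -0.26.

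**Figure D4:**
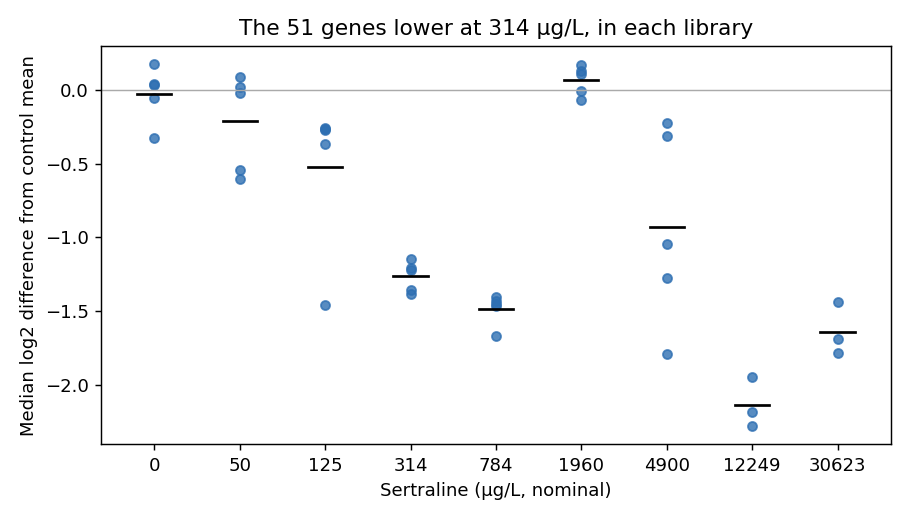
Median log2 difference from the control mean (y axis) over the 51 genes that were lower at 314 µg/L, in each library (points) at each nominal sertraline concentration (x axis, µg/L), with the mean over the libraries of a group as a black bar. The group mean is -1.48 at 784, 0.07 at 1960 and -2.14 at 12249 µg/L.

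Genes called at 784 and at 1960 µg/L were followed to the highest concentration. Of the 159 lower at 784 µg/L, 84 were lower, 16 higher and 59 not called at 30623 µg/L. Of the 54 higher at 784 µg/L, a number that single libraries moved to as low as 30 (without replicate E of 784 µg/L), 9 were higher, 31 lower and 14 not called at 30623 µg/L. Of the 897 lower at 1960 µg/L, 616 were lower and 40 higher at 30623 µg/L. Of the 716 higher at 1960 µg/L, 429 were higher and 73 lower at 30623 µg/L. Of all 7291 genes, 1879 were higher and 2048 lower at 30623 µg/L. The highest expression tercile held 37 of the 54 genes higher at 784 µg/L. In that tercile 409 of 2430 genes were higher and 1303 lower at 30623 µg/L, so falls were common there in any case. These calls share the control libraries, and the differences between the sets were not tested.

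Calls at neighbouring concentrations shared their direction to differing extents. Between 784 and 1960 µg/L, 91 genes were called in the same direction and 34 in opposite directions, where independent lists would share 5.30 higher and 19.6 lower genes and hold 22.3 in opposite directions. Between 1960 and 4900 µg/L the numbers were 1064 and 24, where independent lists would share 106 higher and 168 lower genes and hold 268 in opposite directions. Between 4900 and 12249 µg/L they were 1968 and 18, and between 12249 and 30623 µg/L 2464 and 53, where independent lists would hold 606 and 974 in opposite directions. Of the 53 genes called at 314 µg/L, 52 were called in the same direction at 784 µg/L. These comparisons share the control libraries. Simulated unchanged groups gave a correlation of log2 changes of 0.42 for 784 and 1960 µg/L and 0.33 for 1960 and 4900 µg/L, against 0.26 and 0.71 observed. The covariance was 0.042 observed and 0.013 simulated for the first pair, and 0.24 observed and 0.013 simulated for the second. With the control libraries divided between the comparisons (A and B for the lower concentration, C to E for the higher), the correlations were 0.06 and 0.63. Between 784 and 1960 µg/L 36 genes then shared direction and 13 were in opposite directions, and between 1960 and 4900 µg/L 541 and 4. Simulated unchanged groups shared on average 0 calls in each of these 2 pairs. For the pairs 314 and 784, 4900 and 12249, and 12249 and 30623 µg/L, the observed covariance was 0.052, 0.50 and 0.69, against 0.013 simulated for each, and with divided controls 22, 1284 and 1911 genes shared direction. These correlations and covariances are across genes, which are not independent replicates.

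Over the whole series, 5310 genes (72.8%) differed in at least 1 group in limma's moderated F test, and 4183 had a slope over the concentration rank, 1994 rising and 2189 falling, a majority that turned under centring (2164 rising and 2036 falling) and was larger among genes with a mean of at least 50 (362 rising and 856 falling). Of the 3927 genes called at 30623 µg/L, 12 had been called in the same direction without interruption from 314 µg/L up, 31 from 784, 700 from 1960, 761 from 4900 and 960 from 12249 µg/L, and 1463 were called in that direction first at 30623 µg/L or after an interruption. A further 1531 genes were called at some lower concentration but not at 30623 µg/L, and 317 were called in opposite directions at different concentrations.

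Benchmark concentrations were obtained for 2709 genes. Their median was 1559 µg/L (bootstrap interval 1292 to 1805 over 100 draws). The interval from 784 to 1960 µg/L held 1131 genes (41.7%), and 386 (14.2%) lay at or below 784 µg/L. With the 50 to 784 µg/L means set to the control mean and noise of the measured size added, simulation placed 40.9 genes at or below 784 µg/L. The 25th most sensitive gene lay at 50 µg/L, the lowest tested concentration and the floor of the method, as did 39 genes against 4.85 in the simulation. This value was therefore not resolved from below. Libraries that deviate over many genes together could also raise 39 and 386 above the simulated counts, and whether they did was not tested. Over the genes lower at 314 µg/L, the median against the control mean was -0.61 in A and -0.54 in B at 50 µg/L. It was 0.09 in C, -0.02 in D and 0.02 in E. The excess over the simulation alone therefore does not show how many genes responded at these concentrations. With a departure of 2 residual SD in place of 1, the 25th gene lay at 269 µg/L and the median at 4084 µg/L.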

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

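The tests on the position of the 4900 µg/L libraries, the test on the range of expression at 30623 µg/L and the tests on the genes lower at 314 µg/L were chosen after the results had been seen. Single libraries lay far from the other 4 of their group in 5 of 63 groups of values examined, where chance alone gives about 3.15. Replicate B at 125 µg/L scored 9.45 on the third principal component, against 2.58 to 4.14 in the others, and it is also the library with the lowest median (-1.46) of its group over the genes lower at 314 µg/L. Replicate D at 314 µg/L had 4.49 for Rsub_11992 against 4.24 to 4.31. Replicate D at 1960 µg/L had 5.75 for Rsub_09789 against 4.53 to 4.67. Control replicate E had 8.56 for Rsub_00393 against 9.32 to 9.53, and control replicate B had 9.65 for Rsub_00682 against 9.16 to 9.30.

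The 4900 µg/L libraries spread along the line from the 1960 µg/L mean (0) to the 12249 µg/L mean (1), with A at 0.18, B at 0.30, C at 0.53, D at 0.57 and E at 0.71. A swap of labels with a neighbouring group would need a partner out of place there, and none was seen: the highest 1960 µg/L library, placed without itself, stood at 0.126 and the lowest of the 3 at 12249 µg/L at 0.796, but a swap with a 12249 µg/L library not analysed here stays open. Lower precision without direction would not favour this line, yet 16.5% of the residual sum of squares at 4900 µg/L lay on it, against at most 0.738% in the control and the groups up to 784 µg/L, 0.802% at 1960, 3.78% at 12249 and 10.5% at 30623 µg/L. A steep response near 4900 µg/L, where small differences in exposure move a library far, is a candidate explanation. It was not tested, since measured concentrations were not used here. RNA quality that changes along with the response also stays open, as does a cause tied to the replicate letters, whose order the positions follow.

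At 30623 µg/L, library A lay nearer to each 12249 µg/L library (root mean square log2 difference 0.56 to 0.68) than to C (0.77) or D (0.80). A swap between these groups would put a 12249 µg/L library near C and D, and each of the 3 analysed was farther from both than from its own group, by at least 0.176, but a swap with a 12249 µg/L library not analysed here stays open. Lower depth, with low values pulled towards the gene mean, would concentrate the difference in low genes. In the highest expression tercile the difference was 0.886 to 0.918 times that in the lowest, so it was not confined to low genes. How far depth contributed stays open, since no pair of libraries outside this question gave a ratio for reference. The slope of library minus control on control was negative in every 30623 µg/L library, at -0.225 in A, -0.411 in C and -0.393 in D. These slopes do not by themselves show a contracted range. Quantile scaling gives all libraries the same range. Under it, the lowest expression tercile at 30623 µg/L rose (median log2 change 0.18) and the highest fell (-0.42). In libraries of equal range, large changes of any cause tend to raise low genes and lower high ones. This scaling therefore cannot decide whether the range was contracted. The gap of 0.168 in slope between A and the nearer of the others restates how A differs and tests no cause. A contraction of unequal strength, a single wrong label for A, RNA breakdown in C and D, and unequal progress of toxicity between libraries remain open and were not tested.

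Of the 51 genes lower at 314 µg/L, 29 were higher at 1960 than at 784 µg/L and lower at 12249 than at 1960 µg/L, while 22 of the 51 were still lower than the control at 1960 µg/L. Selection of noise is argued against by the median log2 difference of 1.18 (quartiles 0.68 and 1.75) between 1960 and 784 µg/L, neither of which chose the genes. Low-concentration libraries under a 1960 µg/L label are argued against by the 7.57 times as many genes that differed from the control at 1960 as at 784 µg/L, and centring the libraries moved the median by 1.33% of its size. A first response at low concentration that is replaced by another at 1960 µg/L may account for the course of these genes and stays a hypothesis. Over all 51 genes the library medians did not overlap between 784 (-1.67 to -1.41), 1960 (-0.07 to 0.17) and 12249 µg/L (-2.28 to -1.95). Differences between single libraries of a group would hardly give this separation. An offset shared by all 1960 µg/L libraries, which enter both differences, was not tested. The medians spread from -0.32 to 0.17 in the control and from -0.61 to 0.09 at 50 µg/L. They spread from -1.46 to -0.26 at 125 and from -1.79 to -0.22 at 4900 µg/L.

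Chance was examined by regrouping the libraries of each comparison. At 50 and 125 µg/L the real count was 0, so that all 100 splits gave as many by construction and the comparison shows nothing. The real split alone, 1 of 100, gave as many genes at 314 (53, highest other 13), 784 (213, other 20), 1960 (1613, other 473) and 4900 µg/L (2452, other 1400), for the trend (4183, other 1999) and in the F test (5310, other 1038). It was 1 of 56 at 12249 (3623, other 1357) and at 30623 µg/L (3927, other 1797), the smallest share that 56 splits can give. Chance in the grouping of libraries is thus an unlikely source of these counts. Regrouping cannot test a difference in handling between concentrations, since the labels name no separate cultures. Between 12249 and 4900 µg/L it was also 1 of 56, but by a narrow margin (1557, other 1492), and the real count was 792 without replicate C of 12249 µg/L. Between 30623 and 12249 µg/L there are 10 splits, too few for a share under 0.05, with 2089 genes in the real one and 1622 in the highest other.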

How the results depend on the processing

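Quantile scaling and the fit without the groups from 1960 µg/L up were chosen after the results had been seen. Over 14 results and 92 alternatives other than leaving out a library, 59 stayed within 1.5 times the reported count or 1 SD of the reported value and 33 did not. The 59 include alternatives at 50 and 125 µg/L in which a count of 0 stayed 0. Some of these, such as a minimum log2 change, could not have moved it. Testing only the 1685 genes with a mean of at least 50, which tests fewer genes, gave 24, 113, 656, 874, 1240 and 1276 genes at 314 to 30623 µg/L, 1218 with a trend, 1571 in the F test, 780 between 12249 and 4900 µg/L and 850 between 30623 and 12249 µg/L. A minimum log2 change of 1 gave 91, 371, 759, 1639 and 1949 genes at 784 to 30623 µg/L, and 394 and 699 between the neighbours. The 2 groups alone gave 166 genes (40 higher) at 314, 434 (157 higher) at 784, 417 between 12249 and 4900 and 211 between 30623 and 12249 µg/L. Library weights gave 181 (50 higher) at 314, 482 (169 higher) at 784 and 625 between 12249 and 4900 µg/L. Leaving the groups from 1960 µg/L up out of the fit gave 1 gene at 125, 162 (43 higher) at 314 and 572 (227 higher) at 784 µg/L, against 2 and 54 higher in the reported fit. Centring and quantile scaling kept every gene count within 1.5 times and moved the share of lower genes by under 10 percentage points at each concentration. At 12249 and 30623 µg/L the majority turned under centring, from 1904 lower and 1719 higher to 1749 and 1869, and from 2048 and 1879 to 1939 and 1970, as it did for the trend (2036 falling and 2164 rising). Between 12249 and 4900 µg/L it turned under quantile scaling, from 852 higher and 705 lower to 655 and 743. Leaving out each library in turn gave 792 (without 12249 C) to 1760 genes between 12249 and 4900 µg/L and 1153 (without 30623 D) to 2944 between 30623 and 12249 µg/L, with 1277 without 12249 A and 1247 without 30623 C, and kept the other total counts within 1.5 times. The number higher at 784 µg/L fell from 54 to 30 without 784 E and to 35, 31 and 34 without control A, B or D. At 314 µg/L the number higher moved from 2 to 0 without control D or 314 A, B or C. It was 4 without control E and 6 under quantile scaling. Apart from the number of genes tested and the size of change asked for, the cause was not tested. The 25th benchmark concentration moved from 50 to 269 µg/L with 2 residual SD and to 69.6 µg/L with raw group means. The median moved from 1559 to 4084 µg/L with 2 residual SD, 2112 with a largest change of at least 0.58, 2318 with raw means and 1219 without the highest concentration. The alternative with raw means also took the direction from the highest concentration and kept only genes past the departure there. It placed each at the start of its last unbroken run, so the definition and the genes changed along with the means.

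What libraries of the same letter share is not stated. Same-letter libraries of different groups had a mean correlation of deviations of 0.01, with 19 of 149 pairs over 0.1, and 11 of 41 libraries correlated best with their own letter. With the replicate letter as a block, 50, 205, 1628, 2459, 3644 and 3898 genes were called at 314 to 30623 µg/L, so no count moved by over 1.5 times. Neither check can show an order by letter that is confined to some groups. At 4900 µg/L the libraries stood in letter order between the 1960 and 12249 µg/L means, from A at 0.18 to E at 0.71. So did those at 12249 µg/L, with A at 0.80, B at 0.82 and C at 0.99. Those at 784, 1960 and 30623 µg/L did not. The pseudocount alternatives do not apply to log values, count tests were not run without counts, and the gene lists were not run without gene names. Without counts, how far depth limits the calls of low genes is unknown.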

Other observations

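The breakdown by expression level was chosen after the results had been seen. At 1960 µg/L the lowest expression tercile had 257 genes higher and 121 lower than the control, and the highest had 241 higher and 550 lower. Under quantile scaling these were 223 and 160, and 315 and 470, and under centring 273 and 114, and 253 and 517. Large changes under equal ranges tend to give such a pattern by themselves, so the quantile counts do not test it. At 784 µg/L both ends were mainly lower, with 10 higher and 44 lower in the lowest tercile and 37 higher and 73 lower in the highest. The slope of library minus control on control mean lay between -0.14 and -0.07 in the 5 libraries at 1960 µg/L and between -0.04 and 0.00 in the 5 at 784 µg/L.

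Genes with neighbouring identifiers may respond alike, a hypothesis that assumes that identifier numbers follow position in the genome, which the table does not state. The log2 changes at 12249 µg/L correlated across 4046 pairs of genes whose numbers differ by 1 (r = 0.135, across genes, which are not independent replicates), above all of 1000 random re-pairings (highest 0.055, permutation p = 0.001, the smallest they can give). At a distance of 2 to 5 the correlation across 15819 pairs was 0.033, weaker but still above nearly all re-pairings (highest 0.039, permutation p = 0.002), and at 50 to 60 it was 0.00062 (permutation p = 0.491). Reads shared between directly adjacent genes would give a correlation at a distance of 1 alone. The weak correlation at 2 to 5 did not pass the highest re-pairing, the mark set for that explanation. Its permutation p of 0.002 nevertheless argues against shared reads as the only explanation. A part played by shared reads stays open beside tandem copies and shared regulation, which were not tested.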
